A study of Mus musculus with 40 samples.

How the data were processed

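Each of the 40 samples is a 2-colour array hybridised with total RNA of treated mouse embryos in one channel and of control embryos in the other. Per the labels, the titles carry a replicate number from 1 to 5, a number for the array design (1 or 2), the slide number and a mark that tells a plain readout from a B readout of the same slide. What the B mark stands for is not given in the sources used here. The channel of the treated embryos was taken from the source names of the 2 channels. All 40 arrays form 1 group, treated for 5 h with 40 µM of the drug against control. All value columns were used.

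The deposited values are log2 ratios of one channel over the other. Base 2 is not stated and was inferred from 1 readout, which lacks 786 values and has a long tail of low ratios. That one of its channels lay near background is an assumption, which ratios alone cannot test. In that tail, the values below −3, −4 and −5 had a mean excess of 1.46 ± 0.07, 1.53 ± 0.11 and 1.74 ± 0.18 (SE), against 1.44 expected under it for base 2, 1.0 for natural logarithms and 0.434 for base 10. The estimate moves up in the far tail, so every fold printed assumes base 2. The deposited values were not centred, with array medians from −1.73 to 1.69. Scanner, image software, background correction, normalization and the numerator of the ratio are not given in the sources used here. The ratio was read as channel 1 over channel 2.

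Probes were named through the annotation of the array platform. Symbols were checked through gene identifiers against the GRCm38.p6 gene table, which changed none of them and was used for names only. On array design 1, 4749 probes had 1 gene symbol, 227 several and 2704 none, and 4712 matched the gene table. On array design 2 these numbers were 4935, 275, 2470 and 4884. No name was taken from a probe with several symbols. Spots with the same accession on a design were averaged, which left 7680 and 7599 probes. A gene with several probes was given their mean.

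Each array was centred on its median. The ratios of control-over-treated arrays were turned, readouts were averaged, and the mean of the turned ratios of both orientations, the treatment part, was used as 1 value per replicate, so the arrays of one replicate count once. The mean without turning is the dye part. Probes with values in at least 3 replicates were tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), two-sided, separately within each array design because the tables hold different probes, with Benjamini-Hochberg adjustment and a threshold of 0.05. Of 23 gene lists, those with at least 5 measured genes on a design were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of that design. The lists covered p53 targets, apoptosis, DNA repair, S phase, G2 and mitosis, histones, heat shock and chaperones, endoplasmic reticulum and integrated stress response, NRF2 and glutathione, immediate early genes, ribosomal proteins, proteasome, oxidative phosphorylation, hypoxia and glycolysis, cholesterol synthesis and extracellular matrix. Cell type lists covered erythroid cells, visceral endoderm, neural cells, heart and muscle, mesoderm and neural crest, endothelium, and placenta and decidua. Histones, neural cells, heart and muscle and endothelium had under 5 measured genes on both designs and were not tested as lists. The dye effect was tested in the same way on the dye part, and the slide series difference with a term for series 2000 or 3000.

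The lists, the tests and the rule for named genes were fixed before the data were examined. Named are the 10 probes with the largest rise and the 10 with the largest fall, over both designs, among those past an adjusted p of 0.05 with a single named gene and one sign in every replicate. For each list the up to 3 members with the smallest p among those past the threshold are named, or the 1 with the smallest p where none passed. Cdkn1a, Mdm2, Ccng1, Bax, Trp53, Hspa1a, Hspa1b, Hmox1, Afp and Hbb-y are named where measured.

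Settings varied by plan were no centring, scaling of arrays, other rules on missing values, each readout, each orientation, single arrays with a replicate block, the slide series, robust fits and weights, other thresholds and tests, and leaving out each replicate. Chosen after the data had been seen were removal of a position trend (running median over 101 probe numbers), leaving out the failing readout of replicate 4 on array design 1, and removal of the dye-profile trend. For the last, each replicate's treatment part was fitted as a smooth function of the first 3 principal components of the dye part with mgcv 1.9.3 (scaled t errors, bases of 40 for the first 2 components together and 8 for the last) and the residuals were tested.

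The fits were tested on simulated data with 200 changed probes on each design. Simulated noise was independent between probes and replicates, with each probe's SD left after removal of the trend, equal in all replicates. The median of that SD was 0.0913 and 0.0856, against 0.145 and 0.117 in the real main test. Recovery without a trend therefore holds for less noisy data than the real ones. Without a trend, the main test recovered 82% of 1.25-fold changes on array design 1 and 98% on array design 2, and 100% of 1.5-fold and larger changes, with 14 and 9 false calls. With the estimated trend added to all probes, the main test recovered 44% and 86% of 1.25-fold changes and made 84 and 1502 false calls. The test after removal of the trend recovered 88% and 90% and made 8 and 14. The trend simulated was the one the removal itself had fitted, so this cannot show whether the removal suits the real data. These calls are false only if the trend is no effect of the treatment, which stays open. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.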

Results

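RNA of mouse embryos exposed in culture to 4-hydroperoxycyclophosphamide was compared with RNA of untreated embryos on 2-colour cDNA arrays. The compound is a pre-activated analogue of the DNA-alkylating drug cyclophosphamide, given at 40 µM for 5 h at 37 °C. All 40 arrays carried treated embryos in one channel and control embryos in the other, so they form a single group of comparisons. The probes were spread over 2 array designs of 7680 probes, each with 20 arrays from 5 replicates. Every replicate held both dye orientations on separate slides and 2 readouts of each slide. The number of arrays limits the precision, and the replicates are separate by their labels only, so the p-values measure the spread between these samples, which may be technical. Ratios are given as treated over control, the likely direction, based on the channel order in the labels together with the values of the p53 targets. If the numerator was the other channel, every rise below is a fall and every fall a rise. Changes are relative to the median probe of each array.

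The comparison asked which transcripts differed between treated and control embryos after 5 h. Genes activated by the tumour suppressor p53 made up most of the largest rises. That they rise is no finding of its own, since the direction was chosen in part from them, and with the ratio turned they would be most of the largest falls. Ccng1, the p53 target that encodes cyclin G1, rose 7.44-fold and 5.30-fold on its 2 probes of array design 1 (log2 ratios 2.90 ± 0.46 and 2.41 ± 0.31, SD, n = 5, limma adjusted p = 0.000185 and 0.000115). Its probe on array design 2 rose 2.61-fold (1.39 ± 0.40, SD, n = 5, limma adjusted p = 2.35e-09). Mdm2, the ubiquitin ligase that restrains p53, rose 1.87-fold and 1.86-fold on its 2 probes of array design 1 (0.91 ± 0.41 and 0.89 ± 0.31, SD, n = 5, limma adjusted p = 0.0382 and 0.0196). The p53 targets Rps27l and Aen rose 1.73-fold and 1.68-fold on the same design (0.79 ± 0.25 and 0.75 ± 0.12, SD, n = 5).

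The other probes among the 10 largest rises were Cd81, a tetraspanin of the cell surface, Dnajc9, a histone chaperone, and Rrm2, a subunit of ribonucleotide reductase. Cd81 rose 1.91-fold on array design 2 (0.93 ± 0.19, SD, n = 5), Dnajc9 1.87-fold on array design 1 (0.90 ± 0.16) and Rrm2 1.68-fold on array design 1 (0.75 ± 0.25). The 10 largest falls were smaller. The histone gene H4c18 fell 1.34-fold on array design 1 (−0.43 ± 0.12, SD, n = 5, limma adjusted p = 0.0329). Atf4, the transcription factor of the integrated stress response, fell 1.33-fold on array design 2 (−0.41 ± 0.10, SD, n = 5, limma adjusted p = 9.53e-06). Gmds, Meis1, a homeobox factor, and Racgap1, a cytokinesis gene, fell between 1.20-fold and 1.23-fold on array design 2, with log2 ratios of −0.30 ± 0.11, −0.29 ± 0.14 and −0.26 ± 0.07. Cyth3 fell with a log2 ratio of −0.28 ± 0.21. Ubr3 (−0.39 ± 0.49), Id2 (−0.29 ± 0.31), Spin2c (−0.29 ± 0.29) and Coil (−0.28 ± 0.29) passed the test although their SD was as large as or larger than the mean. In each of them 1 replicate lay far below the other 4. With limma's robust prior for the variance the calls of Ubr3 and Id2 ended (limma adjusted p = 0.249 and 0.092), while Spin2c and Coil kept theirs. All these probes had the same sign in each of the 5 replicates, which the naming rule requires.

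**Figure D1:**
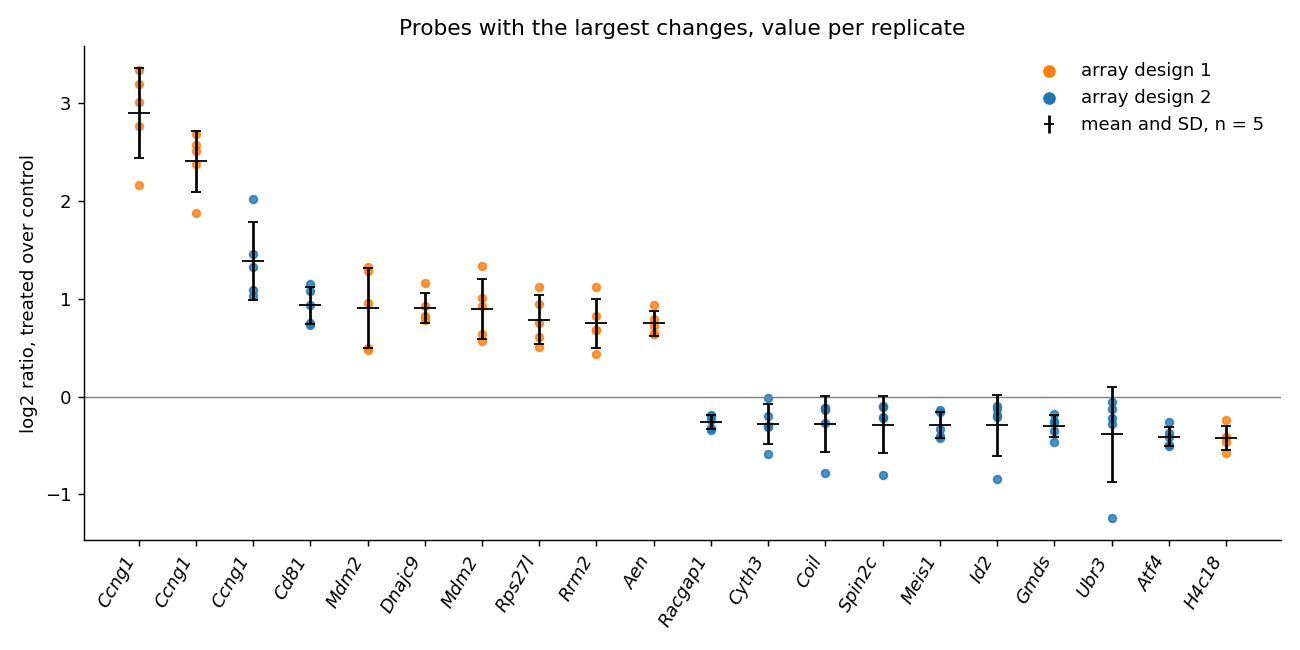
Log2 ratio of treated over control embryos (vertical axis) in each of 5 replicates (points) for the 10 probes with the largest rise and the 10 with the largest fall, with mean and SD. Ccng1 reaches a mean of 2.90 on array design 1 (orange) and 1.39 on array design 2 (blue), and the lowest mean fall is −0.43 for H4c18.

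Of the genes fixed for naming, Hmox1, the haem oxygenase of oxidative stress, had a log2 ratio of 0.47 ± 0.24 (SD, n = 5) on array design 1 and did not pass (limma adjusted p = 0.0516). The embryonic globin Hbb-y rose on each of its 4 probes of array design 2, with log2 ratios from 0.58 to 0.63. Without centring all 4 probes lost the call, at 0.15 to 0.20. They had 0.31 to 0.35 with the dye-profile trend described below removed, where 1 of the 4 probes no longer passed (limma adjusted p = 0.0502). Globin probes can hybridise with transcripts of related globins. Cdkn1a, Bax, Trp53, Hspa1a, Hspa1b and Afp were not named among the probes used here.

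Of 7680 probes on array design 1, 50 passed the test, 49 higher and 1 lower, and 17 of them rose at least 1.5-fold. Of 7599 probes on array design 2, 2114 passed, 1501 higher and 613 lower. Of these, 42 rose and 1 fell at least 1.5-fold. Without centring of the arrays the split turned, with 19 probes higher and 4596 lower on array design 1 and 21 higher and 6634 lower on array design 2. Centring moved the median of all probes by 0.10 to 0.66 on the log2 scale, since the uncentred median of the replicates lay between −0.66 and −0.10. With arrays scaled to one spread, 1150 probes were higher and 180 lower on array design 2. One readout of replicate 4 on array design 1 had lost 786 of 7680 values (10.2%), and 44 of the 50 probes called there were among these. Ccng1, Dnajc9, Rps27l, Rrm2, Aen and the Mdm2 probe with a log2 ratio of 0.91 had the same value with and without this readout. It therefore held no value for them. A call thus went along with a missing value in this readout, whose SD across probes, 1.13, was the largest on that design. Without that readout 1224 probes passed, 781 higher and 443 lower, and all 50 were among them. Leaving out replicate 1, 2, 3 or 5 left 8, 12, 7 or 9 probes on array design 1, and leaving out replicate 4 gave 82. On array design 2, 1013 probes passed without replicate 1, 888 higher and 125 lower. Leaving out replicate 2, 3, 4 or 5 there gave 1254, 1359, 1256 or 1794 higher and 223, 180, 387 or 843 lower.

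Among the named probes of array design 1, only Ccng1, Dnajc9 and Aen kept their calls whichever replicate was left out. The calls of Mdm2 ended without replicate 1, 2, 3 or 5 on one probe (limma adjusted p = 0.0849, 0.0587, 0.0647 and 0.133) and without replicate 1, 3 or 5 on the other (0.061, 0.0647 and 0.0977). Rps27l lost its call without replicate 1 or 3, Rrm2 without replicate 1 or 2, and H4c18 without replicate 1, 2, 3 or 5. Mdm2, Rps27l, Rrm2 and H4c18 also lost theirs with the ordinary one-sample test. With B readouts only, Dnajc9 and Aen lost their calls as well, and Ccng1 alone kept it. All these values kept their sign. On array design 2, Ubr3, Spin2c and Coil lost their calls without replicate 1. The ordinary one-sample test ended the calls of Ubr3, Id2, Spin2c, Coil, Cyth3, Meis1 and 1 Hbb-y probe there. Among list members of array design 1, Pcna, Cdt1, Ftl1, Txnrd1, Rpl37a and Cox7a2l lost their calls without replicate 1, 2, 3 or 5, and Nfe2l2 without replicate 1, 3 or 5.

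The slides belong to 2 numbered series. With a term for the series, 12 probes passed on array design 1 and 1954 on array design 2. Within the 2000 series the counts were 60 and 2172, and within the 3000 series 3 and 811. These rest on 2 and 3 replicates for array design 1 and on 3 and 2 for array design 2, with values in 2 replicates enough for the test, so the counts of the series cannot be compared with each other. Ccng1 was higher in both series, with log2 ratios of 2.47 and 3.18 on one probe of array design 1 and 1.19 and 1.68 on array design 2.

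Part of each replicate's ratios followed the dye profile of the spots, the pattern of their dye component across replicates. The fitted trend took up 34% to 81.5% of the variance of a replicate's treatment part on array design 1. The highest share there was that of replicate 4, which holds the failing readout. On array design 2 the trend took up 35.3% to 61.6%. Treatment part and dye part come from the same arrays, so noise or a different spread of a single array enters both. How much of the trend arose this way was not tested. When this trend was taken out, an alternative chosen after the data had been seen, 382 probes passed on array design 2, 239 higher and 143 lower, of which 257 were called in the same direction before. For array design 1, 60 passed, 43 higher and 17 lower, and 31 were shared. Without the failing readout as well, 118 passed on array design 1. Ccng1 had log2 ratios of 2.64 ± 0.40, 2.20 ± 0.35 and 1.40 ± 0.38 (SD, n = 5) after removal of the trend. The calls of H4c18, Ubr3, Id2, Spin2c and Coil ended, with log2 ratios of −0.25 ± 0.19, −0.05 ± 0.61, −0.35 ± 0.28, −0.29 ± 0.34 and −0.28 ± 0.33, as did that of 1 Hbb-y probe (0.31 ± 0.25).

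The gene lists asked whether groups of genes moved together. By camera, 7 of 19 lists were called higher and none lower on array design 1, and on array design 2, 9 of 15 were called higher and none lower. No list passed with an estimated inter-gene correlation, with lowest adjusted p = 0.434 on array design 1 and adjusted p = 0.198 on array design 2. The same held with the trend removed, with lowest adjusted p = 0.121 and 0.101. Tested alone against 0 with fry, 4 lists passed on array design 1 (3 higher, 1 lower) and 11 on array design 2 (all higher). Once the trend was removed, fry no longer passed oxidative phosphorylation (adjusted p = 0.0641) and placenta and decidua (0.89) on array design 1, nor heat shock (0.138), ribosomal protein (0.209) and proteasome genes (0.564) on array design 2. It then newly passed S phase (0.0299) and G2 and mitosis genes (0.00692) on array design 1, and G2 and mitosis (0.000492) and endoplasmic reticulum stress genes (0.0091) on array design 2.

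Member counts on array design 2 fell for most lists when the trend was removed. Ribosomal protein genes that rose went from 59 to 4, oxidative phosphorylation genes from 28 to 4, extracellular matrix genes from 13 to 3, S phase genes from 13 to 2, heat shock genes from 12 to 2, and NRF2 and glutathione genes from 12 to 5. For proteasome genes the count went from 7 to 0, for p53 targets from 7 to 5, for DNA repair genes from 7 to 3, for apoptosis genes from 5 to 1, for hypoxia and glycolysis genes from 4 to 1, for immediate early genes from 4 to 1, for stress response genes of the endoplasmic reticulum from 4 to 2, and for erythroid markers from 3 to 1. S phase, heat shock, DNA repair and apoptosis then each had 1 member that fell, and the stress response of the endoplasmic reticulum had 2, the same as before. On array design 1, p53 targets that rose stayed at 4, S phase genes went from 5 to 3, NRF2 and glutathione genes from 4 to 3, and ribosomal protein and oxidative phosphorylation genes from 1 to 0, while 1 gene of the endoplasmic reticulum stress response fell. Of the list members named below, 21 lost their call with the sign kept, and 3 more (Fas, Prc1 and Psmd11) changed sign.

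p53 targets had the highest median of the lists on array design 1, 0.51 over 10 measured genes, and were also called on array design 2 with a median of 0.24 over 10 genes. Among the 10 on array design 1, 4 rose and none fell (6 rose and 1 fell adjusted over the list alone), with camera adjusted p = 0.000297 and adjusted p = 0.434 with an estimated correlation. Among those on array design 2, 7 rose and none fell (7 rose adjusted over the list alone), with camera adjusted p = 0.00131 and adjusted p = 0.241 with an estimated correlation. There Ppm1d, the phosphatase that dampens p53 signalling, rose by a log2 ratio of 0.34 ± 0.09 and Aen by 0.32 ± 0.08 (SD, n = 5). After removal of the trend the medians were 0.32 and 0.13, with camera adjusted p = 6.23e-07 and 0.000395, and adjusted p = 0.157 and 0.101 with an estimated correlation.

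S phase genes were called higher on both designs. Of 27 genes on array design 1, 5 rose and none fell (9 rose adjusted over the list alone), with a median of 0.21, camera adjusted p = 8.66e-05 and adjusted p = 0.486 with an estimated correlation. Pcna, the sliding clamp of DNA polymerase, rose by 0.67 ± 0.29, Rrm2 by 0.66 ± 0.26 over its probes, and the origin licensing factor Cdt1 by 0.37 ± 0.13 (SD, n = 5). Of 20 genes on array design 2, 13 rose and none fell (14 rose adjusted over the list alone), with a median of 0.18, camera adjusted p = 0.000167 and adjusted p = 0.398 with an estimated correlation. Prim1, Rfc1 and Mcm6, of DNA priming, clamp loading and the replicative helicase, rose by 0.36 ± 0.11, 0.34 ± 0.11 and 0.34 ± 0.12. After removal of the trend the medians were 0.03 and 0.05 and the list was still called, with camera adjusted p = 0.00129 and 0.00463, and adjusted p = 0.157 and 0.257 with an estimated correlation.

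G2 and mitosis genes were not called by camera, with camera adjusted p = 0.259 on array design 1 and 0.324 on array design 2. None of 30 passed on array design 1, where the smallest p belonged to Nek2 (−0.19 ± 0.04, SD, n = 5, limma adjusted p = 0.0617). The median there was −0.03, the mean 0.00014 and the direction of the test down. Of 26 genes on array design 2, 5 rose and 4 fell (5 and 4 adjusted over the list alone), and the test pointed down with a median of 4.4e-05 and a mean of 0.0054. Prc1 and Ncaph, of the spindle midzone and condensin, rose by 0.35 ± 0.09 and 0.31 ± 0.14, and Racgap1 fell. On array design 1 Prc1 went the other way, at −0.20 ± 0.16 with one sign in all 5 replicates (limma adjusted p = 0.0829 for its probe). After trend removal it had −0.34 ± 0.12 there (limma adjusted p = 0.0157 for its probe) and −0.05 ± 0.06 on array design 2. After removal of the trend the list was called lower on both designs, with medians of −0.11 and −0.08, camera adjusted p = 5.08e-07 and 0.000306, and adjusted p = 0.121 and 0.101 with an estimated correlation. No member then rose, while 3 fell on array design 1 and 8 on array design 2. Adjusted over the list alone, 1 rose and 13 fell on array design 1, and 1 rose and 9 fell on array design 2.

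DNA repair and apoptosis genes were not called by camera on either design, while fry called DNA repair genes higher on array design 2 (adjusted p = 0.0451). Among DNA repair genes none of 29 passed on array design 1, where Fen1 had 0.32 ± 0.20 (SD, n = 5, limma adjusted p = 0.0616), and camera adjusted p was 0.189. Of 21 genes on array design 2, 7 rose and 2 fell (7 and 2 adjusted over the list alone), with camera adjusted p = 0.711 upward, a median of −0.00025 and a mean of 0.068. The mismatch repair gene Msh6 rose by 0.51 ± 0.10, the excision repair gene Ercc5 by 0.36 ± 0.19 and Rpa2 by 0.30 ± 0.22. Among apoptosis genes none of 12 passed on array design 1 (3 rose adjusted over the list alone), where Cycs had 0.38 ± 0.25 (limma adjusted p = 0.0616), with camera adjusted p = 0.108. Of 18 genes on array design 2, 5 rose and 1 fell (5 rose and 2 fell adjusted over the list alone), with camera adjusted p = 0.992. The pro-apoptotic Bik fell by a log2 ratio of −0.23 ± 0.10, and Dad1 and the death receptor Fas rose by 0.22 ± 0.07 and 0.24 ± 0.16. The value of Fas turned to −0.07 with the trend removed and to −0.09 on arrays with treated embryos in channel 1, where the dye part does not cancel.

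NRF2 and glutathione genes, of the defence against oxidants and electrophiles, were called higher on both designs. Of 24 genes on array design 1, 4 rose and none fell (13 rose adjusted over the list alone), with a median of 0.21, camera adjusted p = 0.000119 and adjusted p = 0.434 with an estimated correlation. Ftl1, the ferritin light chain, rose by 0.51 ± 0.19, thioredoxin reductase Txnrd1 by 0.33 ± 0.06 and Nfe2l2, which encodes NRF2, by 0.48 ± 0.23 (SD, n = 5). Of 29 genes on array design 2, 12 rose and 1 fell (14 and 2 adjusted over the list alone), with a median of 0.12, camera adjusted p = 0.00979 and adjusted p = 0.355 with an estimated correlation. Gpx3 rose by 0.55 ± 0.14, Nfe2l2 by 0.48 ± 0.16 and Ftl1 by 0.43 ± 0.09 there. With the trend removed the list was still called, with medians of 0.07 and 0.04 and camera adjusted p = 0.000174 and 0.00583, and adjusted p = 0.157 and 0.154 with an estimated correlation.

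Heat shock and chaperone genes were called higher on both designs. None of 31 passed on array design 1 (12 rose adjusted over the list alone), where Hspa8 had 0.50 ± 0.28 (SD, n = 5, limma adjusted p = 0.0515). The median was 0.19, with camera adjusted p = 7.07e-05 and adjusted p = 0.434 with an estimated correlation. Of 21 genes on array design 2, 12 rose and none fell (12 adjusted over the list alone), with a median of 0.16, camera adjusted p = 0.000689 and adjusted p = 0.241 with an estimated correlation. The chaperones Hspa8, Dnaja1 and Serpinh1 rose by 0.52 ± 0.12, 0.42 ± 0.08 and 0.54 ± 0.32. With the trend removed the medians were 0.04 and 0.07 and the list was still called (camera adjusted p = 0.000678 and 0.0085, and adjusted p = 0.263 and 0.397 with an estimated correlation).

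Genes of the endoplasmic reticulum and integrated stress response were not called by camera, with camera adjusted p = 0.549 and 0.992. None of 23 passed on array design 1 (1 rose adjusted over the list alone), where Canx had 0.39 ± 0.21 (SD, n = 5, limma adjusted p = 0.0556). Of 18 genes on array design 2, 4 rose and 2 fell (4 and 2 adjusted over the list alone), and the test pointed down with a median of 0.02. The folding enzymes Pdia3 and P4hb rose by 0.49 ± 0.10 and 0.29 ± 0.09, while Atf4 fell. Immediate early genes were not called either, with camera adjusted p = 0.619 and 0.462. None of 16 passed on array design 1 (1 rose adjusted over the list alone), where Btg2, an antiproliferative gene that p53 also activates, had 1.08 ± 0.78 (limma adjusted p = 0.0599). The median there was −0.0086, the mean 0.059 and the direction of the test down. Of 8 genes on array design 2, 4 rose and none fell (4 adjusted over the list alone), among them Zfp36l1, Mapk14 and Mapkapk2 by 0.32 ± 0.05, 0.24 ± 0.22 and 0.15 ± 0.13. Without replicate 1, Mapk14 had 0.15 and its call ended, and the call of Mapkapk2 ended without replicate 1, 2, 3 or 4. The last 2 encode stress kinases and are not themselves early response genes.

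Ribosomal protein genes gave the smallest camera p of all lists. All 59 measured on array design 2 rose (59 adjusted over the list alone), with a median of 0.30, camera adjusted p = 1.37e-29 and adjusted p = 0.198 with an estimated correlation. Rps19, Rpl19 and Rpl10a rose by 0.44 ± 0.07, 0.39 ± 0.05 and 0.38 ± 0.06 (SD, n = 5). Of 32 genes on array design 1, 1 rose, Rpl37a by 0.42 ± 0.18, and none fell (29 rose and 1 fell adjusted over the list alone), with a median of 0.32, camera adjusted p = 1.44e-10 and adjusted p = 0.434 with an estimated correlation. With the trend removed the medians were 0.04 and 0.02, and the list was called on array design 1 (camera adjusted p = 0.0226, and adjusted p = 0.473 with an estimated correlation) and not on array design 2 (camera adjusted p = 0.0713).

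Oxidative phosphorylation and proteasome genes were called higher on both designs. Among oxidative phosphorylation genes, 1 of 25 rose on array design 1 (11 adjusted over the list alone), Cox7a2l by 0.32 ± 0.08 (SD, n = 5), with a median of 0.19, camera adjusted p = 4.32e-06 and adjusted p = 0.434 with an estimated correlation. Of 34 genes on array design 2, 28 rose and none fell (30 adjusted over the list alone), with a median of 0.20, camera adjusted p = 6.61e-09 and adjusted p = 0.319 with an estimated correlation. Uqcrc2, Atp5j and Atp5j2 rose by 0.35 ± 0.06, 0.33 ± 0.11 and 0.29 ± 0.07. Among proteasome genes none of 20 passed on array design 1 (9 rose adjusted over the list alone), where Psmb4 had 0.31 ± 0.17 (limma adjusted p = 0.0599), with a median of 0.22, camera adjusted p = 7.07e-05 and adjusted p = 0.434 with an estimated correlation. Of 16 genes on array design 2, 7 rose and none fell (8 adjusted over the list alone), with a median of 0.13, camera adjusted p = 0.0131 and adjusted p = 0.593 with an estimated correlation. Psmd7, Psmc1 and Psmd11 rose by 0.30 ± 0.13, 0.26 ± 0.08 and 0.21 ± 0.08. With the trend removed the proteasome list was called on neither design, with medians of 0.02 and −0.01. Oxidative phosphorylation genes were then called on array design 2 (camera adjusted p = 0.000519, and adjusted p = 0.182 with an estimated correlation) and not on array design 1 (0.0673).

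Extracellular matrix genes were called higher on array design 2, where 13 of 26 rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 0.14, camera adjusted p = 0.00131 and adjusted p = 0.355 with an estimated correlation. The matrix protein Sparc, the gelatinase Mmp2 and the collagen chaperone Serpinh1 rose by 0.44 ± 0.08, 0.43 ± 0.09 and 0.54 ± 0.32 (SD, n = 5). None of 8 passed on array design 1 (1 rose and 1 fell adjusted over the list alone), Sparc had 0.25 ± 0.06 (limma adjusted p = 0.0541), and camera adjusted p was 0.342. On removal of the trend, 3 of the 26 rose and none fell on array design 2, with a median of 0.05, camera adjusted p = 0.000624 and adjusted p = 0.182 with an estimated correlation. Hypoxia and glycolysis genes were not called by camera (adjusted p = 0.166 and 0.462), while fry called them higher on array design 2 (adjusted p = 0.0451). None of 21 passed on array design 1 (2 rose adjusted over the list alone), where Aldoa had 0.32 ± 0.17 (limma adjusted p = 0.0599), and on array design 2, 4 of 11 rose and none fell (4 rose and 1 fell adjusted over the list alone), with Ldhb, Tpi1 and Bnip3l higher by 0.36 ± 0.11, 0.25 ± 0.09 and 0.21 ± 0.11. Among 9 cholesterol synthesis genes on array design 1 none passed (none adjusted over the list alone), with Mvd at −0.20 ± 0.12 (limma adjusted p = 0.0774) and camera adjusted p = 0.345. With the trend removed that list was called lower there, with a median of −0.08, camera adjusted p = 0.0226 and adjusted p = 0.473 with an estimated correlation.

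Markers of blood cells were the only cell type list called by camera. Of 10 erythroid markers on array design 2, 3 rose and none fell (3 adjusted over the list alone), all 3 of them globins, with a median of 0.09, camera adjusted p = 0.0345 and adjusted p = 0.274 with an estimated correlation. Hbb-y, Hba-x and Hbb-b1 rose by 0.61 ± 0.21, 0.58 ± 0.23 and 0.39 ± 0.17 (SD, n = 5). After trend removal these were 0.33 ± 0.22, 0.23 ± 0.23 and 0.19 ± 0.19, and the calls of Hba-x and Hbb-b1 ended (limma adjusted p = 0.0693 and 0.0855). The list was still called then, with a median of 0.06, camera adjusted p = 0.0294 and adjusted p = 0.182 with an estimated correlation. None of 6 passed on array design 1 (none adjusted over the list alone), with Tfrc at 0.24 ± 0.19 (limma adjusted p = 0.0789) and camera adjusted p = 0.694. Markers of visceral endoderm (13 genes), mesoderm and neural crest (5) and placenta and decidua (8) were tested on array design 1 only, with none past the test and camera adjusted p = 0.0584, 0.184 and 0.108. Adjusted over the list alone, none, 1 and 2 of their members fell. By fry, placenta and decidua markers were lower (adjusted p = 0.016), a call that ended with the trend removed (fry adjusted p = 0.89, median −0.008). Their smallest p belonged to Fga (−0.17 ± 0.10, limma adjusted p = 0.0912), Alx1 (−0.20 ± 0.12, limma adjusted p = 0.0745) and Prl8a2 (−0.26 ± 0.12, limma adjusted p = 0.0612).

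Lists with fewer than 5 measured genes on a design were not tested as lists, and only Slbp and Cd34 among their members passed. The histone mRNA binding gene Slbp rose by 0.31 ± 0.10 (SD, n = 5, limma adjusted p = 6.6e-05) on array design 2 and had 0.38 ± 0.20 (limma adjusted p = 0.0541) on array design 1. Cd34, a marker of endothelium, rose by 0.26 ± 0.13 (limma adjusted p = 0.000767) on array design 2, and Cdh5 had 0.22 ± 0.19 (limma adjusted p = 0.1) on array design 1. Both calls ended with the trend removed, with Slbp at 0.02 (limma adjusted p = 0.654) and Cd34 at 0.11 (limma adjusted p = 0.0714) on array design 2. The smallest p on array design 1 belonged to Tubb3 among neural markers (0.36 ± 0.35, limma adjusted p = 0.0926) and to Ckb among heart and muscle markers (0.33 ± 0.64, limma adjusted p = 0.309). On array design 2 it belonged to Vim among neural markers (0.11 ± 0.12, limma adjusted p = 0.139), to Lrp2 among visceral endoderm markers (−0.13 ± 0.09, limma adjusted p = 0.0533), to Mesp2 for mesoderm and neural crest (−0.11 ± 0.02, limma adjusted p = 0.0839), to Bmp2 for placenta and decidua (−0.09 ± 0.07, limma adjusted p = 0.171) and to Srebf1 for cholesterol synthesis (0.05 ± 0.12, limma adjusted p = 0.488).

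**Figure D2:**
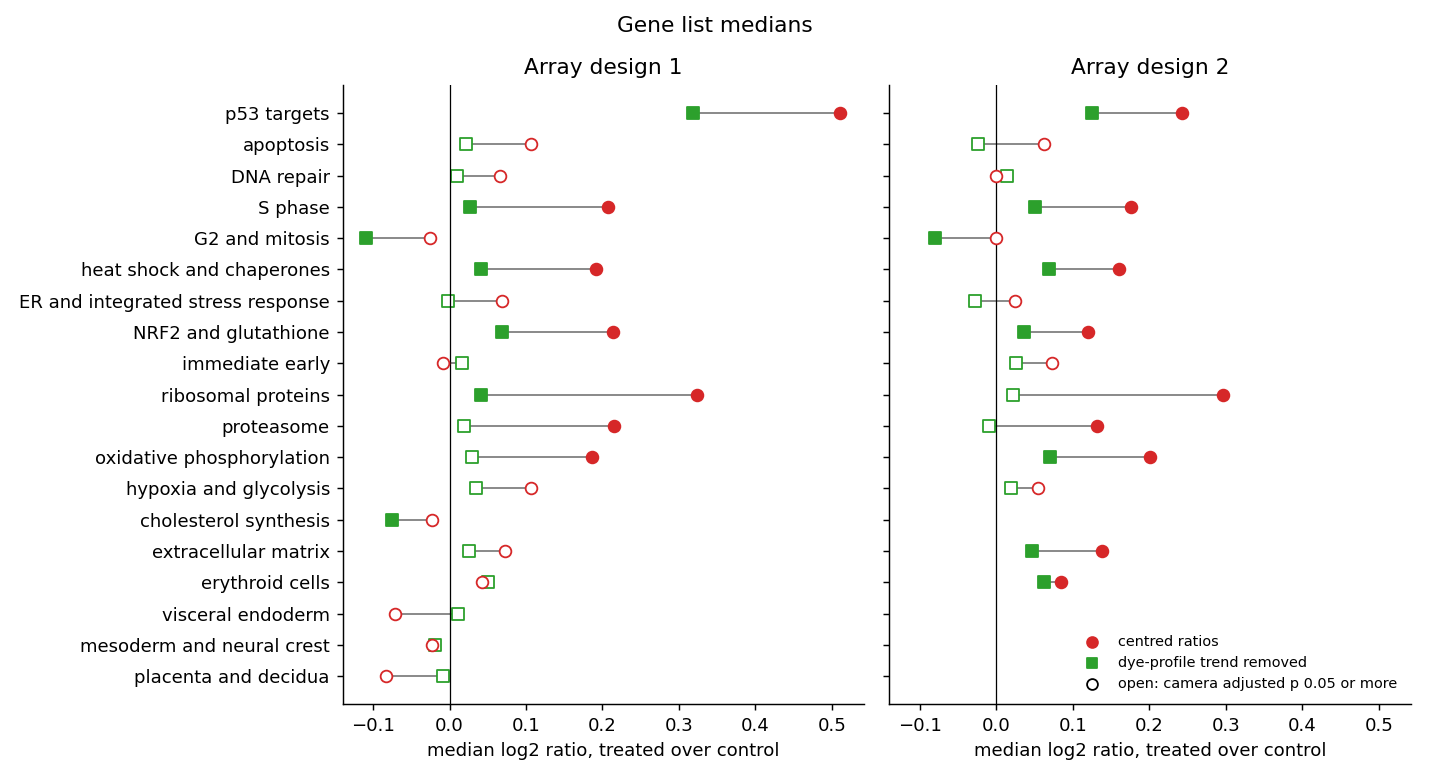
Median log2 ratio of treated over control embryos (horizontal axis) over the measured genes of each list, on array design 1 (left) and array design 2 (right), from centred ratios (red circles) and with the dye-profile trend removed (green squares). Filled symbols passed camera at an adjusted p under 0.05. The ribosomal protein median moves from 0.30 to 0.02 on array design 2, and the p53 target median from 0.24 to 0.13.

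The dye effect, the part of the ratios shared by both orientations, showed how much of a single array's ratio belonged to the channel. Of 7680 probes on array design 1, 1243 passed for it, 1079 brighter in channel 1 and 164 in channel 2 (or the reverse, if the numerator was channel 2). For array design 2, limma called 0 of 7599 probes, with 1431 at an unadjusted p under 0.05. The median SD across probes was 0.37 for the dye part and 0.20 for the treatment part on array design 1, and 0.41 and 0.20 on array design 2. Arrays of one orientation from different replicates correlated from −0.54 to 0.86 across probes on array design 2 and from −0.31 to 0.84 on array design 1. The treatment part of the replicates correlated from 0.35 to 0.69 and from 0.26 to 0.68, and the dye part from −0.39 to 0.88 and from 0.13 to 0.82. The treatment part with the trend removed correlated from 0.22 to 0.49 on array design 2 and from 0.03 to 0.44 on array design 1.

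Between the 2 slide series limma called 0 probes different in their treatment ratio on either design, with 142 of 7680 and 719 of 7599 probes at an unadjusted p under 0.05. Between the array designs, the mean log2 ratios of the 943 genes measured on both correlated across genes with Pearson's r = 0.547 and Spearman's rho = 0.47. Without Ccng1, Pearson's r was 0.489. With the trend removed r was 0.598 and rho 0.354, and r without Ccng1 was 0.459, so the higher r rests on Ccng1. Genes are not independent replicates, and the labels do not say whether replicates of one number share RNA between the designs, in which case this is in part a technical repeat. Among these genes 16 were called on both designs, all 16 in the same direction, against 14 with the trend removed and 7 without centring. Aen and Nfe2l2 illustrate this, with log2 ratios of 0.75 and 0.48 on array design 1 and 0.32 and 0.48 on array design 2.

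**Figure D3:**
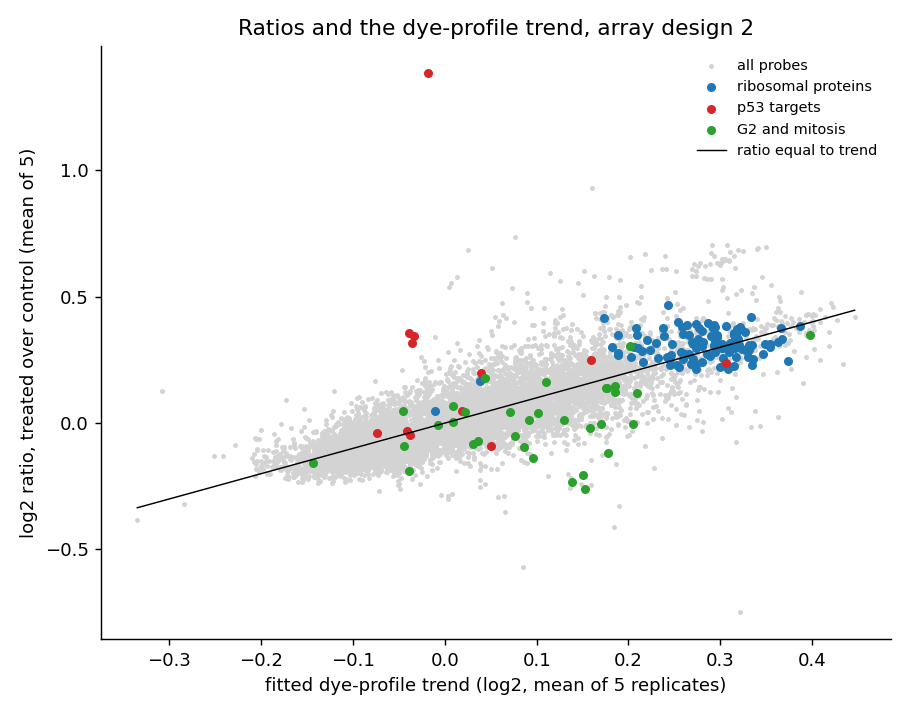
Mean log2 ratio of each probe of array design 2 over 5 replicates (vertical axis) against the fitted dye-profile trend of that probe (horizontal axis, log2), with ribosomal protein (blue), p53 target (red) and G2 and mitosis (green) genes marked. Ribosomal protein probes lie along the line where ratio and trend are equal, while Ccng1 lies at 1.39 far above it.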

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

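Each probe and list member that the naming rule gives, and each list median, was examined for a single replicate far from the other 4 of its 5 replicates, 131 sets of values in all, and 11 stood out. Chance alone marks about 1 in 20 such sets.

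Among the named falls of array design 2, replicate 5 had −1.24 for Ubr3, against −0.284 to −0.0557 in the other replicates, and −0.845 for Id2, against −0.211 to −0.0998. Replicate 1 had −0.798 for Spin2c, against −0.222 to −0.101, and −0.783 for Coil, against −0.267 to −0.116. The globin gene Hbb-b1 on array design 2 had 0.685 in replicate 2, against 0.289 to 0.403 in the others, and Cd34 had 0.492 in replicate 1, against 0.178 to 0.233. For array design 1, Slbp had 0.725 in replicate 5, against 0.262 to 0.326. Ckb had 1.45 in replicate 4, which holds the failing readout, against −0.0543 to 0.152. The median of the endoplasmic reticulum and integrated stress response list on array design 1 was 0.342 in replicate 4, the replicate with the failing readout, against −0.0593 to 0.056. Replicate 1 on array design 2 had a median of 0.301 for oxidative phosphorylation, against 0.168 to 0.192, and of 0.236 for hypoxia and glycolysis, against 0.0188 to 0.0795. Apart from the settings varied for all named values, among them leaving out the failing readout, no technical or biological explanation was tested for these values.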

How the results depend on the processing

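The settings named as position trend, failing readout and dye-profile trend were chosen after the data had been seen. Signal over background could not be read from ratios, so what dim spots limit stays unknown. Settings with a single orientation keep the dye part, which cancels only in the mean of both orientations. Their counts and turns of sign therefore mix treatment and dye. Where no cause is named below, the cause was not tested.

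For array design 1, where 50 probes were called, the count was 4615 without centring (19 higher, 4596 lower), 345 with arrays scaled to one spread, 501 from plain readouts, 3 from B readouts, 2324 (1219 higher, 1105 lower) and 1108 (318 higher, 790 lower) from arrays with treated embryos in channel 1 and in channel 2, and 12 with a slide series term. It was 3 within the 3000 series, 1600 with robust regression (605 higher, 995 lower), 688 with replicate weights (336 higher, 352 lower), 890 with single arrays and a replicate block (684 higher, 206 lower), 5 at an adjusted p under 0.01 and 17 at 1.5-fold. It was 0 over probes with a value on every array, which leaves out 44 of the 50. The ordinary one-sample test gave 68, of which 10 were higher and 58 lower. The count was 1224 without the failing readout, 118 when the dye-profile trend was removed as well, and 9 at 1.5-fold after removal of the trend. Leaving out 1 replicate gave 7 to 82. For array design 2, where 2114 were called, the count was 6655 without centring, 1330 with one spread (1150 higher, 180 lower), 1076 from plain readouts, 1190 and 117 from arrays with treated embryos in channel 1 and in channel 2, 811 within the 3000 series, and 382 with the dye-profile trend removed. It was 869 with the ordinary one-sample test, 1043 at an adjusted p under 0.01, 43 at 1.5-fold and 6 at 1.5-fold after removal of the trend. Leaving out 1 replicate gave 1013 to 2637. The other settings kept each count within 1.5 times. A block that joins both array designs through the replicate number was not run, since each table holds 1 design.

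Of 7 and 9 gene lists called, 0 and 0 were called with an estimated inter-gene correlation, and again 0 and 0 with the trend removed as well. With fry 4 were called on array design 1, where arrays with treated embryos in channel 1 gave 1 and those in channel 2 gave 1. Treated embryos in channel 1 only gave 0 on array design 2. Leaving out 1 replicate gave 7 to 8 lists on array design 1 and 9 on array design 2. The dye effect on array design 2 rose from 0 to 438 probes with B readouts only. The slide series difference stayed at 0, and the correlation between array designs lay between 0.526 and 0.598.

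No named probe turned its direction. Of their values under other settings, 477 kept direction and side of the threshold, 9 gained the call and the rest lost it. Without centring all ratios lie lower, since the uncentred medians were negative in every replicate, and whether that shift is technical was not tested. List members on array design 2 turned there: Ppm1d −0.0849, Aen −0.111, Dad1 −0.21, Fas −0.192, Ercc5 −0.0743, Rpa2 −0.131, Prim1 −0.0659, Rfc1 −0.0889, Mcm6 −0.0881, Prc1 −0.0806, Ncaph −0.123, Dnaja1 −0.0131, P4hb −0.138, Ftl1 −0.00334, Zfp36l1 −0.108, Mapk14 −0.186, Mapkapk2 −0.28, Rpl19 −0.0356, Rpl10a −0.0456, Psmd7 −0.126, Psmc1 −0.172, Psmd11 −0.22, Uqcrc2 −0.0795, Atp5j −0.096, Atp5j2 −0.143, Ldhb −0.0714, Tpi1 −0.183, Bnip3l −0.216, Mmp2 −0.00295, Hbb-b1 −0.0353, Slbp −0.119, Srebf1 −0.376, Vim −0.323 and Cd34 −0.169. With treated embryos in channel 1 only, Rpl37a (array design 1) was −0.00268, Fas −0.0873 and Prc1 −0.300, and the test of the ribosomal list on array design 2 pointed down at a median of 0.0295. With treated embryos in channel 2 only, Rpa2 was −0.000914, Mapkapk2 −0.0107, Psmd11 −0.0416, Hbb-b1 −0.0253 and Slbp −0.137. With the dye-profile trend removed, Fas was −0.0694, Prc1 −0.0493, Psmd11 −0.00573 and the proteasome list on array design 2 −0.0100.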

Other observations

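The tests of the list medians against the dye-profile trend and of the failing readout were chosen after these results had been seen. The comparison of mitotic genes with their nearest spots and the turning of replicates were written before their own outcome. A position below the trend exists only once the trend is fitted, a step chosen after the data had been seen. The comparison of mitotic genes was thus not planned before the data were examined.

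After removal of the dye-profile trend, further genes stood out, chosen after their values were seen. Of those given here, Hmox1, Cd81 and Atf4 are named by the rule and the others are not. Of array design 2, Ckap2, a spindle-associated gene, rose 1.58-fold (0.66 ± 0.10, SD, n = 5), and Ddias, Abhd4, the RNA-binding p53 target Rbm38, Gtse1 and Dcaf4 had log2 ratios of 0.66 ± 0.26, 0.57 ± 0.19, 0.56 ± 0.14, 0.55 ± 0.21 and 0.54 ± 0.21. The tetraspanin Cd151 rose alongside Cd81 (0.48 ± 0.02 and 0.77 ± 0.23). These rises of array design 2 had all passed before removal as well. They were larger then, in the order given 0.74, 0.68, 0.58, 0.61, 0.56, 0.54, 0.59 and 0.93. Hmox1 on array design 1 had 0.47 ± 0.16 and passed (limma adjusted p = 0.0078). Some falls appeared only with the trend removed. The nuclear import gene Kpna2 then had −0.46 ± 0.07 and −0.45 ± 0.08 on its 2 probes of array design 1, and the helicase gene Ddx3x −0.48 ± 0.15 and −0.41 ± 0.11 on its lowest probes, against −0.15, −0.15, −0.21 and −0.11 before (limma adjusted p = 0.342, 0.348, 0.134 and 0.404). On array design 2 the centromeric histone Cenpa, the spindle gene Tacc3, the securin Pttg1 and Hmga2 had −0.37 ± 0.08, −0.35 ± 0.08, −0.30 ± 0.07 and −0.35 ± 0.17. Before, Cenpa and Tacc3 passed at −0.23 and −0.20 (limma adjusted p = 0.00246 and 0.0135), while Pttg1 at −0.12 (0.0855) and Hmga2 at −0.01 (0.91) did not. Atf4 fell 1.51-fold after removal (−0.59 ± 0.08).

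Ribosomal protein genes and p53 targets were set against the dye-profile trend with each list left out of its fit. The ribosomal median was 0.33 ± 0.22 (SD over 5 replicates) before and 0.0385 ± 0.0433 above the trend on array design 1, and 0.30 ± 0.03 before and 0.02593 ± 0.0421 above it on array design 2. Their rise may therefore be one shared by all spots of the same dye profile, and whether that shared rise is technical or a change of abundant transcripts in the embryos stays open and untested. p53 targets lay 0.2698 ± 0.129 above the trend on array design 1 and 0.1495 ± 0.0294 on array design 2, against medians of 0.50 and 0.25 before, which argues against the trend as the whole cause of their shift. No biological explanation was tested for either list.

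G2 and mitosis genes lay below the trend although they were not called before its removal. To see whether the smooth fit made this pattern, each member was compared with the 50 spots nearest in dye profile, with no fit. The mean of the list's median difference was −0.08193 ± 0.0253 (SD) on array design 1 and −0.08658 ± 0.0257 on array design 2, below 0 in all 5 replicates of each, which argues against the smooth fit as the cause. Before removal of the trend the medians were −0.0116 ± 0.0589 and −0.00709 ± 0.0539, within their SD of 0. No biological explanation was tested.

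The count of 50 probes on array design 1 against 2114 on array design 2 was set against the failing readout, the one of replicate 4 that lacks 786 values. Without it 1224 probes were called on array design 1, and with the trend removed as well 118, against 382 on array design 2. Without all of replicate 4, 82 probes were called, while array design 2 gave at least 1013 with any 4 replicates. The readout may thus account for part of the difference, and these counts argue against it as the whole cause. Before adjustment the designs were closer, with 2534 of 7680 and 3128 of 7599 probes at an unadjusted p under 0.05. The median probe SD was 0.145 on array design 1 and 0.117 on array design 2. The prior degrees of freedom in limma, the weight of the variance shared by all probes, were 4.13 and 17.8. Without the failing readout they were 10.4 on array design 1. How far these lower the count was not tested, and what else does stays open.

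With the sign of whole replicates turned, 16 patterns are possible on each design, too few for a share under 0.05. The real pattern called 50 and 2114 probes and the highest of the other patterns 0 on both designs, so 1 of the 16 patterns reached the real count on each. For gene lists, 4 of the 16 patterns reached the real count of 7 on array design 1 and the highest other pattern gave 7. The number of lists called there thus does not set the real pattern apart from turned ones. For array design 2, 1 pattern reached the real count of 9 and the highest other gave 8.

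Before centring, the ratio of treated over control had a median below 0 in each of the 5 replicates of both designs, from −0.66 to −0.12 on array design 2 and from −0.38 to −0.10 on array design 1.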
